A study of Mus musculus with 7 samples.

How the data were processed

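RNA of 7 samples of J-1 mouse embryonic stem cells was hybridised to Affymetrix mouse exon arrays, 1 array per sample: 3 with a luciferase hairpin, 2 with Mettl3 hairpin 1 and 2 with Mettl3 hairpin 2. Per the labels, total RNA was labelled with biotin, and cells had been infected with lentiviruses. The deposited values are log2 expression values of 1201338 exon-level probe sets on each array, and RMA and R 2.11.1 are named in the submitters' processing notes. Over all arrays the values range from 1.44 to 15.05 and array means differ little (6.17 to 6.19), as RMA would leave them. The RMA package, the probe set definition, the genome build of the annotation and any filter are not given in the sources used here. RMA pulls the arrays to a common distribution, so a shift of most transcripts in 1 direction would not be seen. Detection p-values, scan dates and slides are not given in the sources used here either, so scan batches were not examined.

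Gene symbols came from the annotation table of the array platform: 311384 probe sets had 1 symbol, 6385 had several and 883569 had none. Older symbols were updated through the synonyms of a RefSeq gene table of assembly GRCm38.p6 for 45560 probe sets, and 834 kept a symbol that the table does not hold. Chromosomes were taken from the same table; positions are not printed, since the build behind the annotation is not named. Within genes, the variance of probe set log2 fold changes was 0.036 against 0.0638 with names shuffled.

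A gene value was the median, per array, of its probe sets with exactly 1 symbol whose mean over the 7 arrays lay above the median of all probe sets (6.02 on the log2 scale). At least 3 such probe sets were required, which left 229811 probe sets and 16353 genes, with a median of 11 probe sets per gene. No further normalization was applied. Groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on all 7 arrays with 1 mean per group, which leaves 4 residual degrees of freedom. Contrasts were the mean of both hairpins minus luciferase, each hairpin minus luciferase, and hairpin 1 minus hairpin 2. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Intervals are 95% intervals of the same fit.

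The samples, contrasts, tests, 20 gene lists, most alternatives and the rule for named genes were chosen before the data were examined. The lists covered the m6A writer complex, m6A erasers and readers, pluripotency, formative and primed pluripotency, the 2-cell-like state, germ line, mesoderm, endoderm, neuroectoderm, trophectoderm, fibroblast feeder markers, interferon response, p53 targets, cell cycle, immediate early genes, stress and unfolded protein response, glycolysis and hypoxia, chromatin regulators, imprinted genes, and signalling antagonists and targets. Of 421 members, 378 were tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 20 lists. The symbols of 3 list members (Cyr61, Ctgf and Ero1l) were updated in the same way as the array annotation, after a first list result had been seen; the result with the symbols as written is given beside it. Exon usage was tested with limma's diffSplice over the kept probe sets of each gene.

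Named genes are Mettl3; for both hairpins, the 10 largest changes per direction among called genes whose 4 knockdown arrays lie beyond all 3 luciferase arrays; for each hairpin and between hairpins, the 5 largest per direction by the same rule; up to 4 called members of each list with the largest change, or the 2 largest differences where none passed; and the 5 genes with the smallest exon usage p. Predicted genes, clones, and Olfr, Vmn, Mir and Snor genes were skipped in naming and kept in counts. Klf2, Parva and the other genes outside this rule were named after their values were seen.

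Agreement of the hairpins was set beside 100 simulations of unchanged groups against the same controls. The analysis was tested on simulated probe sets for the comparison of both hairpins with luciferase, with 16353 genes and the fitted (moderated) spreads: 100% of genes changed by 1 on the log2 scale and 57% of those changed by 0.5 were called, and 6.16% of calls were unchanged genes. In the exon usage test 100% of 200 genes with 2 probe sets changed by 1.5 were called, and 12.7% of calls were genes without such a change. With unmoderated spreads these shares were 91%, 23%, 2.92%, 98.5% and 29.1%. The moderated spreads were chosen after a result with unmoderated ones had been seen. The alternatives were other filters on dim probe sets, a mean or median polish in place of the median, quantile normalization or centring, other spread models, a replicate block, single groups, a fold change threshold and leaving out each array. A crossed replicate block, the list symbols as written, a component of the within-group residuals as a covariate and separate luciferase arrays for each hairpin were added after seeing the data. Probe sets with several symbols or none were left out of the gene comparisons. Figures were drawn with matplotlib 3.10.9.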

Results

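Gene expression was measured in J-1 cells, a male line of mouse embryonic stem cells, after infection with lentiviruses that carried short hairpin RNAs. A hairpin against luciferase, an insect gene that mouse cells lack, served as the control in 3 samples. Hairpin 1 against Mettl3 was used in 2 samples and hairpin 2 against Mettl3 in another 2. Mettl3 encodes the catalytic subunit of the complex that places N6-methyladenosine, or m6A, on RNA. Each sample was hybridised to 1 exon array, which carries separate probe sets for single exons, and values are on the log2 scale. The 7 arrays had nearly equal overall levels, with medians of 6.03 to 6.07 over 1201338 probe sets. The first principal component of the 16353 gene values (41% of the variance) placed the 3 luciferase arrays at -17.7 to -13.7 and the 4 knockdown arrays at 7.26 to 16.4. The next component (21.4%) set luciferase replicate 3 and hairpin 1 replicate 2 apart from the others (-10.4 and -17.8), so it did not follow the groups. The labels do not say whether samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision.

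The first comparison asked whether each hairpin lowered its target. Mettl3, on chromosome 14, was at 10.33 ± 0.16 (SD, n = 3) with the luciferase hairpin, 8.82 ± 0.21 (SD, n = 2) with hairpin 1 and 8.69 ± 0.03 (SD, n = 2) with hairpin 2. It fell 2.83-fold with hairpin 1 (log2 fold change -1.50, limma adjusted p = 0.000361) and 3.11-fold with hairpin 2 (-1.64, adjusted p = 0.000424). The mean of both hairpins was -1.57 ± 0.105 (SE) from the control, and all 4 knockdown arrays lay below all 3 control arrays. The hairpins did not differ detectably in the extent of knockdown (0.14, 95% interval -0.17 to 0.44, adjusted p = 0.843). Of the 17 kept probe sets of Mettl3, 13 were lower by 1 or more on the log2 scale and 3 lay within 0.25 of no change.

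The main comparison set the mean of both Mettl3 hairpins against luciferase, which shows the gene expression that goes with lower Mettl3 RNA in these cells; METTL3 protein and m6A were not analysed here. Among the genes with the largest rises were Dppa3 (log2 fold change 1.37 ± 0.106, SE), which encodes a maternal factor active in the germ line and early embryo, and Ina (1.30 ± 0.073, SE), which encodes the neuronal intermediate filament alpha-internexin. Fndc3c1, an X-linked gene (1.47), the lysosomal amidase gene Naaa (1.20), the semaphorin gene Sema6a (1.19), the X-linked zinc finger gene Zfp280c (1.15) and the peptidase gene Pm20d2 (1.15) rose as well. Bhlhe40, a basic helix-loop-helix repressor gene, rose by 1.23 and Kdm5d, a Y-linked histone demethylase gene, by 1.33; with hairpin 2 alone they were at 0.73 (adjusted p = 0.0737) and 0.45 (adjusted p = 0.0829). The kappa-casein gene Csn3 rose by 1.56, a value that rests on 3 kept probe sets and was -0.11 (adjusted p = 0.69) when dim probe sets were included. Pm20d2 was at 0.20 (adjusted p = 0.29) with the stricter filter on dim probe sets.

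Septin1, a septin GTPase gene, fell the most (-1.58 ± 0.085, SE), followed by Mettl3 itself. Morc1, which acts in transposon silencing in male germ cells (-1.22), the ribosomal protein gene Rpl39l (-1.14), the RNA helicase gene D1Pas1 (-1.08) and Gsg1 (-1.04) fell. Dusp27 (-1.05), the surface antigen gene Gpa33 (-1.03), the amino acid decarboxylase gene Ddc (-1.03) and the membrane protein gene Emp1 (-1.03) also fell. Limma adjusted p-values of these 20 genes ranged from 6.93e-05 to 0.00255.

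**Figure D1:**
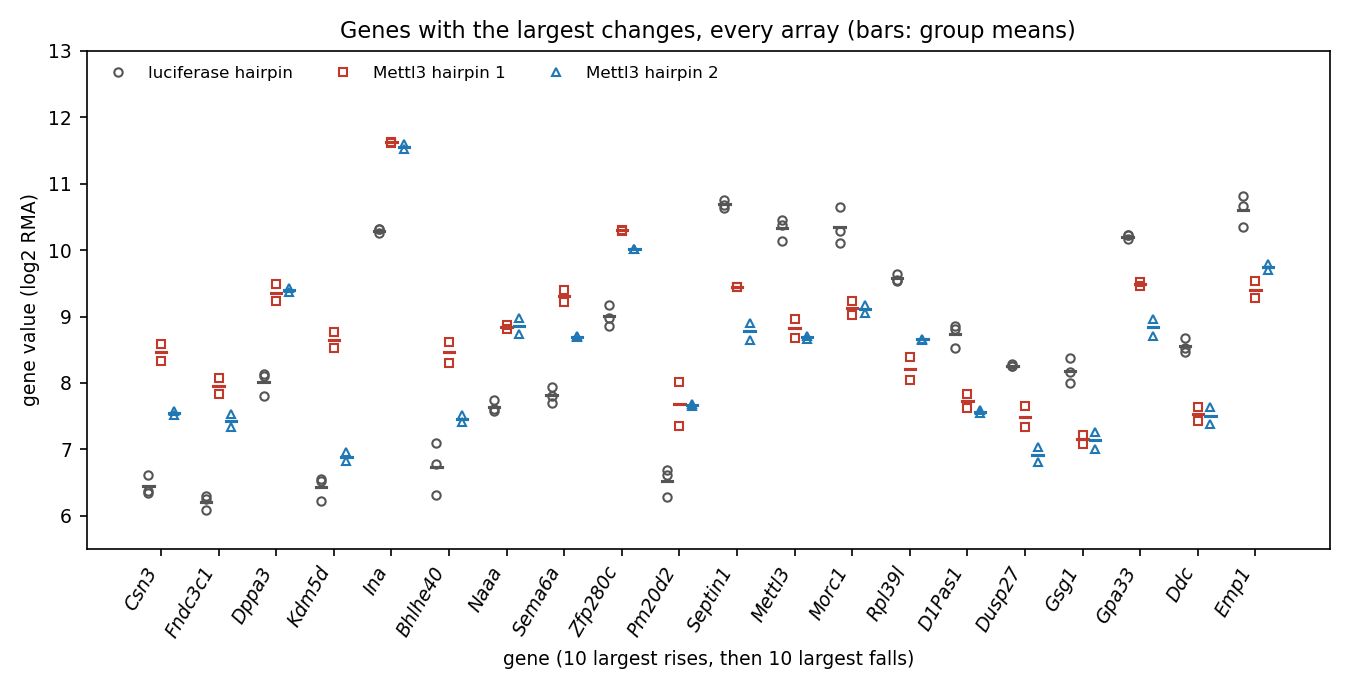
Gene values (log2 RMA) of the 10 genes per direction with the largest changes under the rule for named genes, on every array. Circles are luciferase arrays, squares hairpin 1 and triangles hairpin 2, and bars are group means; for each gene the 4 knockdown arrays lie on 1 side of all 3 luciferase arrays, and Kdm5d means are 6.44, 8.64 and 6.89 in that order.

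Of 16353 genes tested, 1292 changed at an adjusted p below 0.05, and 904 of them rose and 388 fell. Most changes were small: the median size among called genes was 0.45 on the log2 scale, and 27 genes rose and 15 fell by at least 2-fold. The split by direction depended on scaling, since 696 genes rose and 703 fell once each array was centred on its median gene value. The count was 638 without luciferase replicate 1, 817 without luciferase replicate 3, 804 without hairpin 1 replicate 1, 846 without hairpin 2 replicate 1 and 605 without hairpin 2 replicate 2.

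The 20 gene lists fixed before the data were examined held 378 tested members. Of 9 tested members of the m6A writer complex, only Mettl3 passed, and the same gene alone passed when p-values were adjusted over the list alone (median 0.13, mean -0.07, camera direction up). Wtap, another subunit, was at 0.32 (adjusted p = 0.0919), but its kept probe sets moved apart, with a median change of 0.11. None of the 12 tested erasers and readers of m6A passed, also when adjusted over the list alone; the 2 largest differences were Fto, an eraser gene (0.27, adjusted p = 0.0628), and Hnrnpa2b1 (-0.25, adjusted p = 0.171).

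Genes of the pluripotent state moved both ways. Of 28 pluripotency genes, 3 rose (Dppa3, the Nodal antagonist gene Lefty1 at 0.75 and the naive state factor Klf2 at 0.37) and 2 fell (the naive state factors Tbx3 at -0.62 and Gbx2 at -0.51). Adjusted over the list alone, 4 rose and 4 fell. The median of this list was -0.06 and its mean 0.02, with camera direction down. Of 14 genes of formative and primed pluripotency, 5 rose and 1 fell (5 and 1 adjusted over the list alone): Sall2 rose by 0.67, the growth factor gene Fgf5 by 0.46 and the DNA methyltransferase gene Dnmt3b by 0.41, while the ETS factor gene Etv4 was at -0.43. With the stricter filter, Fgf5 was at -0.08 (adjusted p = 0.58), and the calls of Fgf5 and Dnmt3b were lost when either of 2 single arrays was left out. None of 6 tested genes of the 2-cell-like state passed (also adjusted over the list alone), the largest differences being Tmem92 (-0.23, adjusted p = 0.17) and Sp110 (0.15, adjusted p = 0.471).

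Markers of differentiated lineages and of feeder cells formed 5 lists. Of 15 neuroectoderm genes, 3 rose and 1 fell (7 and 2 adjusted over the list alone): Map2 (0.77) and Nefl (0.60), both of the neuronal cytoskeleton, and the neural progenitor filament gene Nes (0.46) rose, and Sox1 was at -0.39. The keratin genes Krt18 (1.03), Krt8 (0.81) and Krt19 (0.43) were the 3 of 15 trophectoderm genes that rose, and none fell (3 and 1 adjusted over the list alone; median -0.02, mean 0.11, camera direction up). Of 19 mesoderm genes 1 fell, the VEGF receptor gene Kdr (-0.44), and of 22 endoderm genes 1 fell, the endocytic receptor gene Cubn (-0.76); both counts were 1 adjusted over the list alone. Of 17 fibroblast markers, which would mark feeder cells in the dish, Acta2 (1.07) and Tagln (0.78) rose, both of which encode contractile proteins, and no collagen gene passed (3 rose and 0 fell adjusted over the list alone; median -0.11, mean 0.05, camera direction down). The rotation test fry, unlike camera, called the neuroectoderm and trophectoderm lists higher and the endoderm list lower (adjusted p = 0.032 each). Fry tests a list against no change and camera tests it against the other genes, so the 2 tests answer different questions. Tagln was at 0.36 with hairpin 2 alone (adjusted p = 0.0851). Nes was at -0.15 (adjusted p = 0.27) with the stricter filter. Calls of Sox1 and Kdr were lost when any of 6 single arrays was left out, that of Krt19 for 5 and that of Nes for 4.

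Imprinted genes, which are expressed from 1 parental copy, rose as a list: 7 of 25 rose and none fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00011, and adjusted p = 0.58 with an estimated correlation). Examples are the zinc finger gene Plagl1 (0.83), the noncoding RNA gene Kcnq1ot1 (0.66) and Phlda2, which restrains placental growth (0.52). Plagl1 was at -0.22 (adjusted p = 0.1) with the stricter filter, and the call of H19 (0.45) was lost without any of 5 single arrays and, at 0.39, after centring. H19 was at -0.21 with hairpin 1 (adjusted p = 0.401) and rose by 1.11 with hairpin 2 (adjusted p = 0.00377). Immediate early genes were higher as a list, with 5 of 20 up and 1 down (8 and 2 adjusted over the list alone; camera adjusted p = 0.047, and adjusted p = 0.58 with an estimated correlation). The transcription factor genes Klf6 (0.53), Atf3 (0.53) and Jun (0.49) rose and Myc fell by 0.43. Stress and unfolded protein response genes were higher as a list, with 3 of 21 up and none down (7 and 0 adjusted over the list alone; camera adjusted p = 0.047, and adjusted p = 0.58 with an estimated correlation): Vldlr (0.46), the glutathione-degrading enzyme gene Chac1 (0.44) and the mitochondrial folate enzyme gene Mthfd2 (0.33). The germ line list was lower, with 2 of 14 down, Mael (-0.94) and Dazl (-0.88), which act in transposon silencing and in translation in germ cells (2 up and 7 down adjusted over the list alone; camera adjusted p = 0.047, and adjusted p = 0.75 with an estimated correlation). The call of Mthfd2 was lost when any of 6 single arrays was left out, that of Atf3 for 4 and that of Myc for 2.

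The fry test called the imprinted, immediate early and stress lists (adjusted p = 0.032 each) and not the germ line list (adjusted p = 0.13). The camera call of the germ line list was lost without luciferase replicate 2 (adjusted p = 0.11), hairpin 1 replicate 2 (0.13) or hairpin 2 replicate 1 (0.19). That of the immediate early list was lost without luciferase replicate 2 (0.15), hairpin 1 replicate 2 (0.12), hairpin 2 replicate 1 (0.063) or hairpin 2 replicate 2 (0.07). That of the stress list was lost without luciferase replicate 1 (0.051), luciferase replicate 2 (0.11), hairpin 1 replicate 1 (0.099), hairpin 2 replicate 1 (0.063) or hairpin 2 replicate 2 (0.07). These 3 calls were also lost after quantile normalization (0.05 each) and after centring (0.098, 0.06 and 0.098). With list symbols as first written, without updating 3 older names, only the imprinted list passed; adjusted p was 0.051 for the germ line and stress lists and 0.11 for the immediate early list.

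Among targets of signalling pathways, 4 of 24 rose and 1 fell (4 and 1 adjusted over the list alone). Ptch1 (0.86) and Gli1 (0.71) are transcribed in response to Hedgehog signalling, Socs2 (0.56) to cytokine signalling and Hey1 (0.40) to Notch signalling. Chromatin regulator genes included 3 of 25 that fell and none that rose (0 and 4 adjusted over the list alone): the deacetylase gene Hdac2 (-0.43), Dnmt3l (-0.34) and the Polycomb gene Eed (-0.29), whose calls were lost without any of 5, 6 and 7 single arrays. The interferon response list had 2 of 19 genes lower, Xaf1 (-0.51) and the RNA sensor gene Ddx58 (-0.36), and none higher (2 up and 3 down adjusted over the list alone). Among 23 p53 targets, Perp rose by 0.47 and Ei24 fell by 0.43 (1 and 1 adjusted over the list alone), calls that were each lost without any of 3 single arrays, as was that of Ddx58 for 2 and that of Hey1 for 1. The oxygen sensor gene Egln3 (0.65) was the 1 of 24 genes of glycolysis and hypoxia that rose, and none fell (1 and 0 adjusted over the list alone). None of 26 cell cycle genes passed, also adjusted over the list alone, and the largest differences were Top2a (-0.22, adjusted p = 0.206) and Cdk1 (-0.19, adjusted p = 0.257). Camera adjusted p-values of the 16 lists not called ranged from 0.11 to 0.84.

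**Figure D2:**
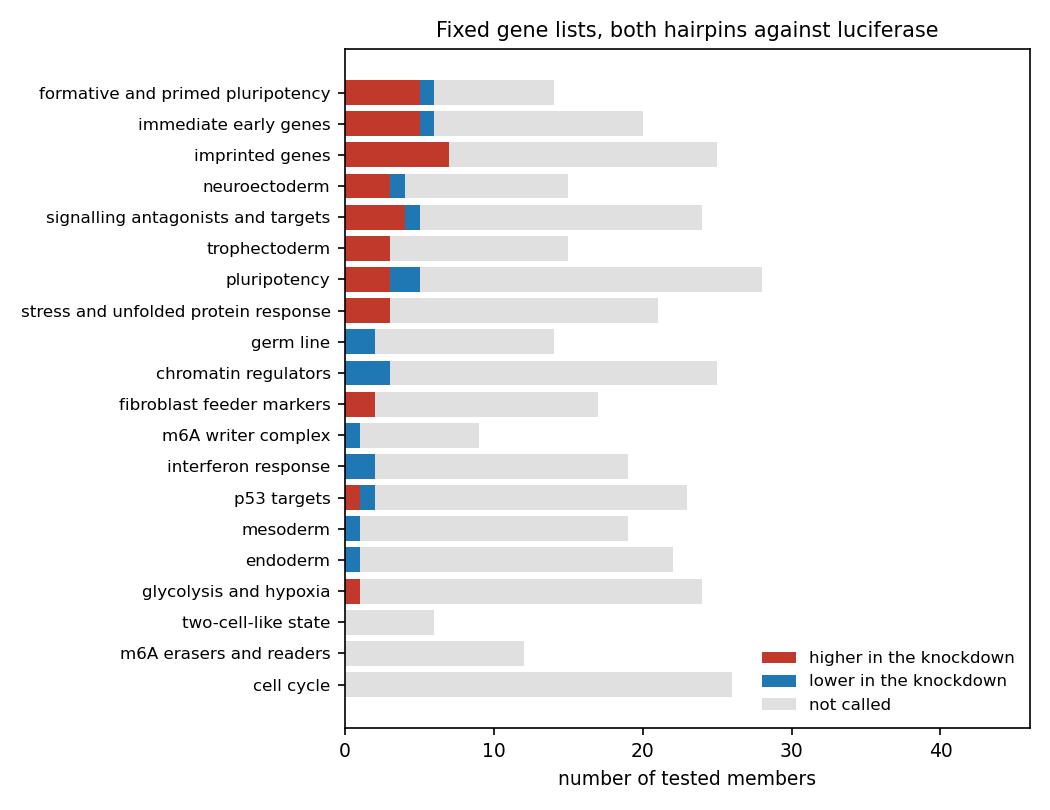
Number of tested members of each fixed gene list that were higher (red), lower (blue) or not called (grey) for the mean of both Mettl3 hairpins against luciferase. The imprinted list has 7 members higher and none lower, and no cell cycle gene was called.

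Each hairpin was then compared with luciferase alone. With hairpin 1, Kdm5d (log2 fold change 2.21 ± 0.125, SE) and Csn3 (2.02) rose the most, followed by Fndc3c1 (1.73), Bhlhe40 (1.73) and Sema6a (1.49). The largest falls were Mettl3 (-1.50), Rpl39l (-1.36), Septin1 (-1.24), Morc1 (-1.21) and Emp1 (-1.20). In all, 649 genes rose and 315 fell, 964 together (578 and 566 after centring). Without hairpin 1 replicate 1 the count was 271, without hairpin 1 replicate 2 it was 450 and without luciferase replicate 1 it was 460.

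With hairpin 2, Dppa3 (1.39), Ina (1.27), the X-linked gene Glod5 (1.27), Fndc3c1 (1.21) and Naaa (1.21) rose the most. Septin1 (-1.91), Mettl3 (-1.64), Gpa33 (-1.36), Dusp27 (-1.34) and the X-linked tumour antigen gene Trap1a (-1.24) fell the most. In all, 443 genes rose and 176 fell, 619 together (326 and 256 after centring). Without hairpin 2 replicate 2 the count was 63, without hairpin 2 replicate 1 it was 121, without luciferase replicate 1 it was 246 and without luciferase replicate 3 it was 343. The imprinted list was higher with both hairpins (camera adjusted p = 0.0025 for hairpin 1 and 5.8e-05 for hairpin 2, and 0.64 and 0.77 as adjusted p with an estimated correlation). The germ line list was lower with hairpin 1 (median -0.33, camera adjusted p = 0.0016, and adjusted p = 0.64 with an estimated correlation) and did not pass with hairpin 2 (median -0.05, camera adjusted p = 0.5). The immediate early list was higher with hairpin 1 (camera adjusted p = 0.0083, and adjusted p = 0.64 with an estimated correlation) and did not pass with hairpin 2 (0.32), and the stress list passed with neither (0.05 and 0.17).

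Of the 54 list members called for the mean of both hairpins, 23 passed with each hairpin, Dppa3, Tbx3, Dazl, Mael, Map2, Krt18, Kcnq1ot1 and Ptch1 among them. With hairpin 1 only, 20 passed, among them Lefty1, Sall2, Dnmt3b, Nes, Kdr, Krt19, Tagln, Klf6, Atf3, Jun, Myc, Vldlr, Chac1, Hdac2, Dnmt3l, Socs2, Ddx58 and Ei24. With hairpin 2 only, 3 passed (Klf2, Perp and H19), and 8 passed with neither alone, among them Sox1, Mthfd2 and Eed.

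Whether 2 hairpins of different sequence gave like changes was examined across genes. Of the genes called, 300 rose and 99 fell with both hairpins (225 and 162 after centring), Ina, Dppa3, Naaa, Ptch1, Parva, Dazl and Morc1 among them, and 0 were called in opposite directions. Independent lists of these sizes would share 17.6 and 3.39 genes, but these lists are not independent, since both rest on the same 3 luciferase arrays. Simulated groups without an effect against the same controls shared 0, but such groups yield few calls by construction, so this 0 sets no scale for the shared calls. Over all genes, 74.6% had the same sign with both hairpins, against 63.1% in the simulation. Log2 fold changes correlated across genes, which are not independent replicates, at Pearson r = 0.718 against 0.400 in the simulation, and their covariance was 0.0374 against 0.00581. The simulation drew the noise of each gene independently, whereas 1 component held 41.9% of the real within-group variance. Real groups without an effect could therefore lie further from the simulated values. Part of the correlation comes from the 3 shared luciferase arrays, since the simulated groups without an effect were also correlated. With 1 luciferase array for one hairpin and the other 2 for the other, an analysis added after the data were seen, r was 0.396 to 0.561 (mean 0.502) and the covariance 0.0254 to 0.033 (mean 0.0302) over the 6 possible ways. The share of genes with the same sign was then 60.4% to 67.3%. No simulation was run for separate luciferase arrays. The 63.1% above holds for shared ones and is no reference for these shares. Fold changes that share no array would not correlate through noise that is independent between arrays, though noise common to several arrays could still make them correlate. The number of shared calls was 56 without hairpin 2 replicate 2, 94 without hairpin 2 replicate 1, 153 without hairpin 1 replicate 1, 246 without hairpin 1 replicate 2, 156 without luciferase replicate 1 and 222 without luciferase replicate 3.

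**Figure D3:**
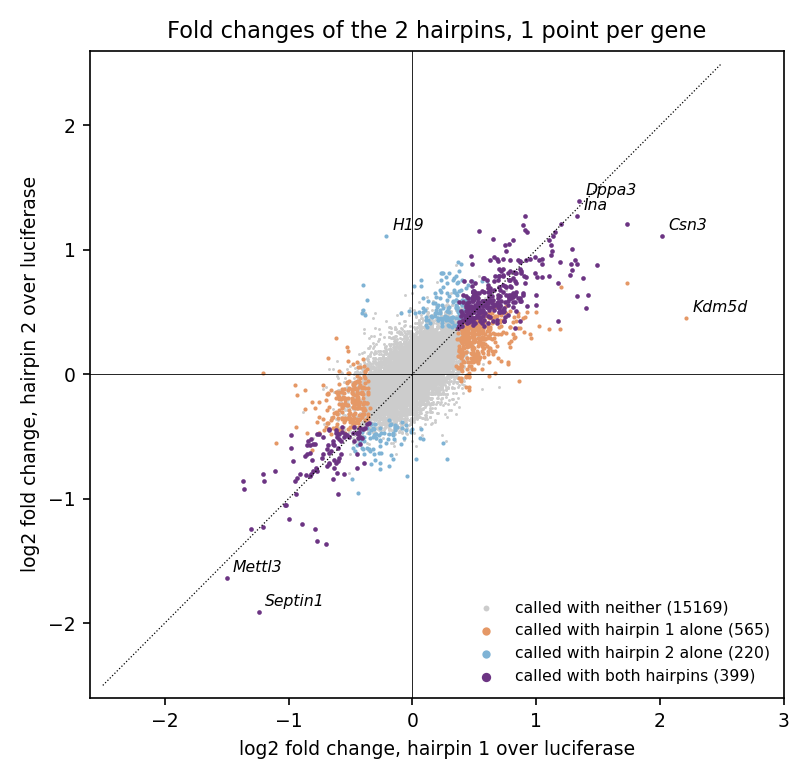
Log2 fold change over luciferase of each of 16353 genes with hairpin 1 (horizontal) and hairpin 2 (vertical); purple points are the 399 genes called with both hairpins and the dotted line marks equal change. Mettl3 and Septin1 lie far below 0 on both axes, and Kdm5d is at 2.21 with hairpin 1 and 0.45 with hairpin 2.

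The difference between the hairpins was tested directly, and 17 genes passed, of which 9 were higher and 8 lower with hairpin 1. Kdm5d was higher with hairpin 1 by 1.75 (adjusted p = 0.003), Csn3 by 0.91, the AMPA receptor accessory gene Shisa6 by 0.87, Tagln by 0.83 and the lens crystallin gene Cryga by 0.80. The imprinted noncoding RNA gene H19 was lower with hairpin 1 by 1.32 on the log2 scale (-1.32, adjusted p = 0.0269), Plac8 was at -1.12, the BMP target gene Id2 at -0.90, Serpinb1a at -0.86 and the small GTPase gene Mras at -0.76. Apart from Kdm5d, the genes named here had adjusted p between 0.0269 and 0.0438. At most 4 genes passed when any single array was left out, and 0 without hairpin 2 replicate 2, where Kdm5d was at 1.69 (adjusted p = 0.082).

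Probe sets of 1 gene were compared with each other as a measure of exon usage; their positions are not given in the sources used here, so they were not placed in exons. Wtap, the writer complex subunit, had 31 kept probe sets that moved apart: 9 rose above 0.5, up to 0.94, 7 lay below -0.25, down to -0.56, and the rest lay between (exon usage adjusted p = 5.16e-22). The 8 brightest Wtap probe sets, at 12.67 or more, differed by 0.02 to 0.09. In Patj, a cell polarity gene, probe sets ranged from -0.07 to 2.00, and in Rims1, a synaptic active zone gene, from -0.41 to 1.14. Probe sets of the tropomyosin gene Tpm1 ranged from -0.01 to 1.71 and those of Plagl1 from -0.32 to 3.45, where the highest has a luciferase mean of 5.16, below the filter level, so that its size is uncertain. In all, 813 genes passed the limma exon usage test for both hairpins against luciferase, of which 368 had also changed at the gene level. Mettl3, the hairpin target, passed too (limma exon usage adjusted p = 2.69e-15). Its kept probe sets at 7.83, 7.44, 7.14 and 6.26 with luciferase were at -0.12, 0.04, -0.52 and 0.23, against a median of -1.39. A call can thus come from dim probe sets that follow the change of a gene less, and need not mean altered exon usage. Another split of the arrays, which parts the luciferase arrays, gave 892 genes, so the count is not firm. In simulated data with 200 genes changed in this way, 12.7% to 29.1% of exon usage calls were false. That share depends on the number of changed genes and on the simulated noise, so it need not hold for the real calls. The 5 genes named had adjusted p from 0.32 to 1 in that other split, and the count was 281 without hairpin 2 replicate 2, 483 without hairpin 2 replicate 1 and 376 without luciferase replicate 1.

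**Figure D4:**
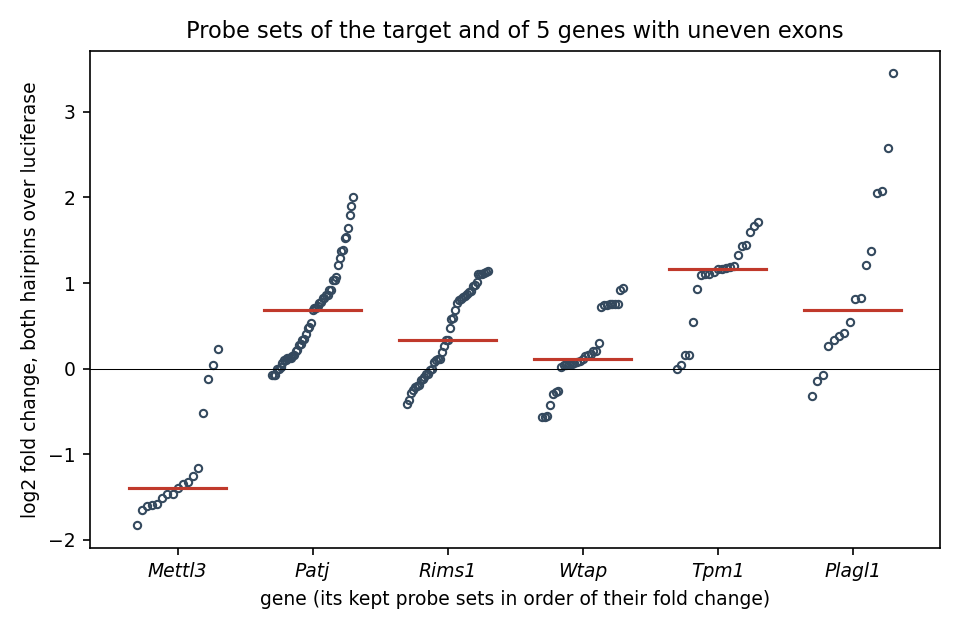
Log2 fold change (both Mettl3 hairpins over luciferase) of each kept probe set of Mettl3 and of the 5 genes with the smallest exon usage p-values. Points are probe sets in order of their fold change and red bars are medians, -1.39 for Mettl3 and 0.11 for Wtap.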

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

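In this part, the tests of fewer cells with a Y chromosome and of feeder fibroblasts were chosen after the values they use had been seen; those of X-linked homologues and of further actin genes were prompted by the data, with the outcome set down before it was computed.

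The test of the difference between hairpins picked out 17 genes. Higher with hairpin 1 on the log2 scale were Kdm5d (1.75), Csn3 (0.91), Shisa6 (0.87), Tagln (0.83), Cryga (0.80) and the keratin genes Krt18 (0.78) and Krt8 (0.75). Lower with hairpin 1 were H19 (-1.32), Plac8 (-1.12), Id2 (-0.90), Serpinb1a (-0.86) and Mras (-0.76). The other 5 of the 17 were the Y-linked gene Eif2s3y (0.78, adjusted p = 0.0448), Plin2 (0.69), Steap3 (-0.70), Gm26504 (-1.21) and 6330410L21Rik (-0.92). Among the gene lists, the germ line list was lower with hairpin 1 than with hairpin 2 (median -0.33, camera adjusted p = 0.00022), and the fibroblast (0.0014) and immediate early (0.011) lists were higher; adjusted p = 0.6 for each of the 3 with an estimated correlation. Probe sets outside the gene comparisons also changed for the mean of both hairpins against luciferase: 123 of 361791 without a symbol (75 up and 48 down) and 119 of 3954 with several symbols (69 up and 50 down). The largest of them, a probe set without a symbol, was at -3.44 ± 0.19 (SE, limma adjusted p = 0.00326).

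Compared with luciferase, the Y-linked genes did not move together. Between hairpins, Kdm5d, Eif2s3y and Uty were all higher with hairpin 1 (means 8.64 against 6.89, 10.17 against 9.39 and 8.44 against 7.48). Limma adjusted p for these differences was 0.003, 0.045 and 0.06. Uba1y, Tspy-ps, Ssty1 and Ssty2 also had higher means with hairpin 1, and Usp9y and 1700040F15Rik had lower ones. Eif2s3y and Uty were lower than luciferase with hairpin 2 (-0.82 and -0.68, adjusted p = 0.0039 and 0.025), and their changes differed by -0.14 ± 0.17 (SE). Fewer Y-bearing cells in those cultures would lower both alike. These 2 genes were picked after their falls were seen, so their likeness does not test that explanation. Kdm5d showed no such fall with hairpin 2. It was above luciferase by 0.45 ± 0.12 (SE), which did not pass (limma adjusted p = 0.083), and with hairpin 1 by 2.21. Its brightest kept probe set was at -0.18 with hairpin 2. The largest rises with hairpin 2 among its kept probe sets, 1.85 and 1.43, had luciferase means of 4.33 and 4.48, below the filter level. The Kdm5d change with hairpin 2 is therefore uncertain and does not decide the question of fewer Y-bearing cells. The other 6 tested Y-linked genes did not pass with hairpin 2. Tspy-ps was at -0.33, Ssty1 at -0.25, Ssty2 at -0.22, Uba1y at -0.19, 1700040F15Rik at -0.09 and Usp9y at 0.08. Whether these 6 genes are expressed in these cells was not tested, so they leave the question of fewer Y-bearing cells undecided. The X-linked homologues Eif2s3x (-0.02 with hairpin 2) and Kdm5c (0.03 with hairpin 1) stayed apart from their Y-linked genes by at least 0.80 ± 0.14 (SE), which argues against cross-hybridization. A hairpin-specific effect on Kdm5d stays open as a hypothesis, and the labels hold nothing that tests it.

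Acta2 and Tagln rose for the mean of both hairpins against luciferase; Tagln did not pass with hairpin 2 alone (0.36, adjusted p = 0.0851). More feeder fibroblasts would raise the collagen and other fibroblast genes too, and the other 15 markers had a median of -0.13 (95% bootstrap interval -0.14 to -0.01), below the bound of 0.39 set from the smaller of the 2 changes. With hairpin 1 alone, where Acta2 and Tagln rose most, that median was -0.06 (95% bootstrap interval -0.15 to 0.16, bound 0.59), although the marker Loxl1 rose by 0.47 (adjusted p = 0.0317). A list of 30 other actin and contractile genes, chosen from general knowledge after the rise of Acta2 and Tagln was seen and before the list was tested, was higher than other genes (9 up and 0 down, median 0.17, camera p = 4.6e-06, and p = 0.035 with an estimated correlation). Neither p-value was adjusted for the number of added lists. A wider rise of actin and contractile genes in the knockdown is a candidate explanation, on the same 7 arrays that prompted it.

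Other splits of the 7 arrays into groups of 3, 2 and 2 were compared with the real one, in 100 of the 105 possible splits. For genes changed for the mean of both hairpins, 1 of the 100 splits, the real one with 1292 genes, gave as many; the highest other gave 1078 and kept the 3 luciferase arrays together, and every split drawn that parted them gave 0. The 2 splits with any genes make the same parting of luciferase from knockdown arrays. A split that parts the luciferase arrays puts any difference between the groups into the spread, which lowers its count. Since 7 arrays can be parted in few ways, the count makes chance less likely for the real parting and does not exclude it. Chance between cultures was not tested. For exon usage, 2 of the 100 splits gave as many as the 813 genes of the real one, and the highest other gave 892. That split set luciferase replicates 1 and 3 and hairpin 1 replicate 2 against the rest, and 17 splits that part the luciferase arrays gave over 100 genes, so the arrays have a structure besides their groups. The real calls and those of that split shared 34 genes, with 44.4 expected of independent lists. For gene lists, 5 of the 100 splits called as many as the real 4, so chance is not excluded for their number.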

How the results depend on the processing

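The crossed replicate block, the list symbols as written, the residual component and separate controls were chosen after seeing the data. Mettl3 fell under every alternative run, between -1.66 and -1.50 on leaving out single arrays. Of 1673 comparisons of 99 named gene results with an alternative, 1460 kept direction and side of the threshold, 204 lost the call, 5 gained one and 4 reversed; of 399 list comparisons 354 kept both, 35 lost and 10 gained a call. The reversals were Csn3 (-0.11 without a filter) and, with the stricter filter, Fgf5 (-0.08), Nes (-0.15) and Plagl1 (-0.22). Dim probe sets enter without a filter and leave with the stricter one. The brightest Plagl1 probe sets, at luciferase means of 9.38, 9.32 and 9.22, were at -0.32, -0.07 and -0.14. Its largest rises, 3.45 and 2.58, were in probe sets at 5.16 and 6.09, below the stricter level of 7.57. For the other reversals the cause was not tested further. Counts below are for both hairpins, hairpin 1, hairpin 2, between hairpins and shared calls, against 1292, 964, 619, 17 and 399. Without a filter on dim probe sets they were 484, 320, 92, 0 and 73, with r = 0.632 between hairpins (19993 genes tested). With the stricter filter the last 4 were 1503, 1073, 34 and 699, and 2 lists passed instead of 4 (12271 genes). A mean of probe sets gave 2840, 2259, 1626, 79 and 1079 with 7 lists, and median polish 2469, 2072, 1439, 76 and 951 with 7 lists. Array weights gave 1288 with hairpin 2 and 1 list, trend and robust settings 29 between hairpins, and a minimum change of 0.5 gave 473 for both. Lists called were 1 after quantile normalization, 1 after centring, 1 with symbols as written and 0 with an estimated correlation. The residual component as a covariate, which removes spread by construction, gave 2029, 1638, 992, 8 and 648, with 1 list and 2381 exon usage genes, the 813 reported ones included. Replicate numbers showed no sign of pairing the samples: deviations of same-numbered samples correlated at -0.26 to 0.08. In groups of 2 samples the 2 deviations mirror each other, so few of these values are independent and pairing is not excluded. With the replicate block the counts were 540, 460, 208, 3 and 138, and 261 for exon usage; with crossed numbers they were 542, 389, 151, 0 and 102. Leaving out 1 array gave 605 to 1098, 271 to 729, 63 to 577, 0 to 4 and 56 to 268, with r from 0.581 to 0.743, 1 to 4 lists and 281 to 944 exon usage genes. An arm of 1 sample is then assumed to vary like the other groups. Of the lists, 1 passed without luciferase replicate 2 or hairpin 2 replicate 1, and 2 passed without hairpin 1 replicate 2 or hairpin 2 replicate 2; r was 0.581 without hairpin 1 replicate 1. With separate luciferase arrays for each hairpin, so without shared controls, r was 0.502. The cause of these moves was not tested, except that fewer arrays leave less power. The 2-cell-like list had too few genes to test with the stricter filter. No detection p-values were used; of the 3271 dimmest genes 80 rose and 90 fell, against 277 and 95 of 3271 in the middle.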

Other observations

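The test of a gain of X copies was chosen after its result had been seen; the other tests in this part were prompted by the data, with the outcome set down before it was computed.

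Genes on the X chromosome were over-represented among those that rose. Of 561 X-linked genes tested, 66 rose for the mean of both hairpins (11.8%), against 834 of 15740 autosomal genes (5.3%; odds ratio 2.38, two-sided Fisher's exact p = 4.9e-09, adjusted over 20 chromosomes 9.9e-08). Fndc3c1, Zfp280c and Glod5 are among them, as are Fhl1 (0.88), a LIM domain gene, and Msn (0.47), which links actin to the membrane. With hairpin 1, 45 X-linked genes rose, and with hairpin 2, 44. For the mean of both hairpins the count was 38 without luciferase replicate 1 (6.77%, against 2.81% of autosomal genes). Without a filter on dim probe sets it was 35 of 781 (4.48% against 1.68%). The share of X-linked genes that fell was 2.5%, not detectably different from autosomes (two-sided Fisher's exact adjusted p = 1). Of the other chromosomes, 17 had fewer genes that rose (25 of 809, adjusted p = 0.012) and 12 fewer that fell (2 of 554, adjusted p = 0.0059). The odds ratio for the X chromosome was 2.75 without a filter, 2.21 with the stricter filter, 2.69 after centring and 2.45 to 2.97 on leaving out single arrays.

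Several explanations of the X-linked excess were tested. Draws of autosomal genes matched on expression level and number of probe sets held a median of 29 risen genes (95% range 20 to 40), below the 66 observed. Such draws also take genes as independent, so their range may be too narrow. A gain of X copies would lift X-linked genes together, and their median lay only 0.012 above that of autosomal genes (95% bootstrap interval -0.005 to 0.036). Neighbouring genes rising as blocks do not account for it either, since 55 separate runs of adjacent risen genes remained, the longest of 3 genes. The excess may be biological, as a hypothesis found and tested on the same 7 arrays, in which scan batches were not examined.

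Germ line genes beyond the fixed list were also lower. A list of 42 further germ line genes, chosen from general knowledge after Dazl and Mael were seen to fall and before the list was tested, had 36 tested members, of which 8 fell and 3 rose (median -0.10, camera p = 0.0029, and p = 0.17 with an estimated correlation). These p-values, too, were not adjusted for the number of added lists. The piRNA pathway helicase gene Mov10l1 (-0.55), the transcription factor gene Sohlh2 (-0.63), Tex14 (-0.47), and the meiotic chromosome genes Sycp2 (-0.48), Hormad1 (-0.44) and Stag3 (-0.32) fell, whereas Mei4 (0.58), Tdrkh (0.53) and Ddx25 (0.36) rose. Sycp2, Hormad1 and Stag3 did not pass with hairpin 2 alone (adjusted p = 0.462, 0.127 and 0.349), nor Tex14, Tdrkh and Ddx25 with hairpin 1 alone (0.0798, 0.193 and 0.49). A wider fall of germ line genes is a candidate explanation for the fall of Dazl and Mael, and it stays a hypothesis, since with the estimated correlation the list did not pass.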
